A study of Mus musculus with 6 samples.

How the data were processed

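Bulk RNA sequencing was carried out on liver from C57BL/6J mice that received a high-fat diet, with 60% of calories from fat, from 5 weeks of age for 21 weeks. The obese mice had been sorted by haematoxylin and eosin histology into isolated steatosis, in which the liver stores fat, and nonalcoholic steatohepatitis (NASH). The groups are therefore histological classes of animals on 1 diet and not a treatment. Per the labels, 3 hepatic samples per group were picked at random. They are taken here as samples of separate mice, which the labels state only by implication. No lean group was analysed here, so no value can be set against a healthy liver.

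Per the labels' protocols, libraries were made from polyadenylated RNA and sequenced as pairs of 150 bp reads on an Illumina HiSeq instrument. The submitters' processing notes name TopHat2 and HTSeq, without versions, and the mm10 (GRCm38) mouse genome. The annotation release, the strand setting and the treatment of reads shared by several genes are not given in the sources used here. The deposited files hold raw counts of reads per gene, whole numbers that were not normalized, for 39179 Ensembl gene identifiers in each of the 6 libraries. A gene symbol was found for 37607 identifiers. The 1572 others held between 0.07% and 0.12% of the counts of a library. Coordinates are from the GENCODE M21 annotation of GRCm38. Because strand use in counting is not given, reads of genes that overlap on opposite strands could not be told apart. Of the 87 genes selected by the rule given later in this section, 25 share exon positions with another annotated gene and 16 of these overlap a gene on the opposite strand. Members of gene families with near-identical copies, such as Cyp4a, Cyp2a, Cyp2b, Ces1, Acot and Mup genes, may have split reads between copies, and their values are uncertain for that reason.

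Counts were analysed in R 4.3.3. Genes with low counts were removed with the default filter of edgeR 4.0.16, which left 11375 tested genes. Library sizes were scaled with TMM factors, which ranged from 0.79 to 1.5. NASH was compared with steatosis by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are those of the model, and the standard error (SE) of a log2 fold change was taken from its size and the F statistic, an approximation. Levels are CPM values (counts relative to a TMM-scaled library size), given as the mean ± SD of 3 libraries. Shifts of 36 gene lists, fixed from general knowledge of liver biology and not chosen on these samples, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at the preset correlation between genes of 0.01. The 32 lists with at least 4 tested members were tested, two-sided, and adjusted together. Camera with a correlation estimated from the data and fry, a test of a list by itself, were alternatives. A single value per library was compared by a two-sided exact permutation test. With 3 libraries against 3 the smallest p it can give is 0.1.

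The lists, the tests and the rule for named genes were set before the data were examined. The rule took the 15 genes higher and the 15 lower with the largest fold change among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted models, pseudogenes and antigen receptor segments. It added up to 4 members with the smallest p of each list that camera called, and a panel of 25 genes whatever their result. Some genes that were tested are not reported here. Other genes in the text were chosen after their values were seen. For a called gene with 10 or fewer counts summed over a group, a ratio of NASH over steatosis is given. It is the ratio of the summed counts after each was divided by the summed TMM-scaled library sizes of its group. Its exact 95% interval covers counting error only.

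On counts simulated from the measured means, dispersions and library sizes for the comparison of NASH with steatosis, over 11157 genes, the test recovered 23.2% of genes changed 2-fold and 91.9% of those changed 4-fold, out of 200 changed genes. Of its calls 5% were false, and 0 had the wrong sign. In the simulation, most 2-fold changes of single genes were missed. The changed genes were drawn from those with a mean log2 CPM of at least 0, so recovery at lower counts is not known. Genes were simulated independently of each other, so the false share does not account for genes that vary together. The Benjamini-Hochberg cut also depends on how many genes change. In the data 548 genes were called, against 200 changed in the simulation, so recovery in the data may differ.

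The alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors and upper-quartile factors in edgeR, no filter and a stricter filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, each library left out in turn, other thresholds, and other tests of the lists. A further 4 alternatives were chosen after seeing the data, because mitochondrial and ribosomal RNA (rRNA) reads differed between libraries. They left out those loci, scaled without TMM, kept only the 4 libraries with few rRNA reads, or used the rRNA share as a covariate. Direction under an alternative was read from the mean log2 fold change of a list. Camera's own direction was tried first and the rounded mean next, and both changes were made after those values had been seen. No library was left out of the comparison itself.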

Results

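Gene expression was measured in 6 livers of mice on a high-fat diet, 3 with isolated steatosis and 3 with NASH, in which steatosis is joined by inflammation and cell injury. Total gene counts were 16855316, 14883514 and 18002095 in the steatosis libraries and 15762050, 17577354 and 13909238 in the NASH libraries. Most counts came from mitochondrially encoded genes, which took 77.9%, 68.3% and 70.6% of the steatosis counts and 81.8%, 83.9% and 62.0% of the NASH counts. Reads at 4 loci that carry rRNA-like sequence (Gm42418, Gm23935, Gm26917 and Lars2) made up 22.3% of NASH 3 and 8.96% of steatosis 2 but between 0.60% and 1.06% of the other libraries. All other genes were left with 3595795, 3378730 and 5149189 counts in steatosis and 2707334, 2719869 and 2185922 in NASH. Their share was 24.2% ± 3.87 in steatosis and 16.1% ± 0.929 in NASH (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Within groups, log2 CPM correlated across genes at 0.938 to 0.963, and between groups at 0.902 to 0.940. Pairs of libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 38.3.

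**Figure D1:**
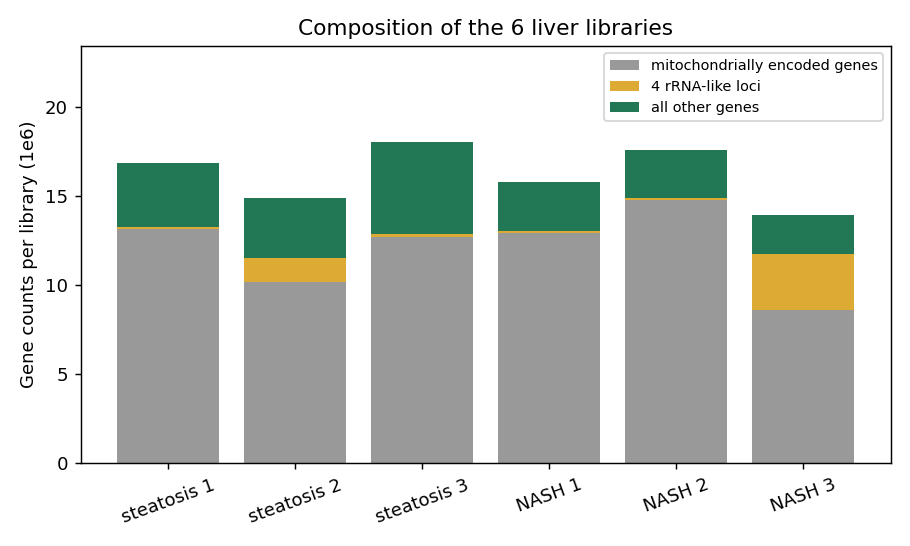
Stacked bars give the gene counts of each liver library (vertical axis), split into mitochondrially encoded genes, 4 rRNA-like loci and all other genes. Mitochondrially encoded genes fill between 62.0% and 83.9% of each bar, and the rRNA-like loci stand out in NASH 3 and steatosis 2.

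The comparison of the groups asks which liver genes differ between obese mice whose histology had progressed to NASH and those with fat storage alone. By camera with its preset correlation, genes of cholesterol and fatty acid synthesis tended to be higher in NASH, and those of fatty acid oxidation, drug metabolism and antioxidant defence lower. With an estimated correlation none of these 5 shifts passed (adjusted p = 0.27, 0.39, 0.39, 0.19 and 0.32), and of 30 antioxidant genes 8 fell and 1 rose by edgeR's test. Of 11375 tested genes, 169 rose and 379 fell in NASH by edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. At least a 2-fold change was seen in 129 of the higher and 275 of the lower genes. The groups did not overlap for 545 of the 548 called genes. Over all tested genes 29.3% did not overlap, against the 10% that chance gives. Scaled to the counts of other genes without TMM, the split was 179 higher and 222 lower, with a shift of the median log2 fold change of all genes from 0.01 to 0.12. Each fit with 1 library left out also has fewer libraries by construction, and the loss of power was not separated from the influence of that library. The numbers of calls varied with the library left out. They came to 39 higher and 77 lower without steatosis 1, 29 and 85 without steatosis 2, 61 and 120 without NASH 1, 74 and 127 without NASH 2, and 89 and 137 without NASH 3, against 170 and 298 without steatosis 3. In the 4 libraries with few rRNA reads, 17 were higher and 19 lower. Of the 54 called genes that the naming rule took, 19, 20 and 5 lost their call without steatosis 1, 2 and 3, and 21, 13 and 18 without NASH 1, 2 and 3. The 26 that passed in each of these 6 fits included Acly, Sqle, Fasn, Chrna4, Nsdhl, Gnat1 and Fdps among the higher, and Cd36, Tomm40l, Nr1i3, Eci1, Cyp7a1, Prdx1, Osbpl5, Pcp4l1, Ephx1, Fmo2, Acot4, Aldh1a1, Ech1, Retsat, Gpx1, Cyp4a10 and Acot1 among the lower.

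Camera called 11 of the 32 lists tested, 5 towards higher and 6 towards lower expression in NASH. With a correlation between genes estimated from the data none of the 32 passed (adjusted p = 0.19 or more), though 3 had an unadjusted p under 0.05. Fry called 6 lists in 1 direction and 18 when members could move either way. The 6 were cholesterol synthesis, fatty acid synthesis, drug metabolism, oxidative stress, female-biased and sphingolipid genes, the last not called by camera. Of camera's 11, fry in 1 direction missed the fatty acid oxidation (adjusted p = 0.0517), droplet (0.0794), unfolded protein (0.112), interferon (0.114), mitochondrial (0.204) and endothelial (0.33) lists. Camera's preset correlation treats the genes of a list as nearly independent.

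The list of cholesterol synthesis genes, which SREBP2 controls, was called higher in NASH by camera, though fewer members passed singly than did not. Of the 24 listed genes 11 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 0.99 (camera adjusted p = 1.21e-12; adjusted p = 0.27 with an estimated correlation). Fdps and Mvd, enzymes of the mevalonate pathway, rose by 3.50 (SE 0.37, edgeR adjusted p = 0.00293) and 3.45 (SE 0.55, edgeR adjusted p = 0.0115) on the log2 scale, the Mvd call being lost without steatosis 1 or 2. Nsdhl, of the later sterol steps, rose from 2.92 ± 0.712 to 18.4 ± 4.52 CPM (SD, n = 3 each, edgeR adjusted p = 0.00275). Sqle, the squalene epoxidase, rose by 2.96 (SE 0.35, edgeR adjusted p = 0.00374). Fdps shares exon positions with a predicted gene on the same strand.

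The list of fatty acid and triglyceride synthesis moved the same way. Of its 28 genes 10 rose and 0 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.89 (camera adjusted p = 1.68e-06; adjusted p = 0.39 with an estimated correlation). Fasn, the fatty acid synthase, rose from 16.9 ± 1.78 to 181 ± 111 CPM (SD, n = 3 each, log2 fold change 3.42, SE 0.43, edgeR adjusted p = 0.00423). Its NASH values of 301, 160 and 82.4 CPM all lay above the steatosis range. Acly, which makes cytosolic acetyl-CoA, rose by 2.65 (SE 0.27, edgeR adjusted p = 0.00275). Scd1, which desaturates stearoyl-CoA, rose by 1.43 (SE 0.30, edgeR adjusted p = 0.0288) and Acacb by 2.02 (SE 0.46, edgeR adjusted p = 0.0371), but neither call was stable. Scd1 did not pass without steatosis 2, steatosis 3, NASH 1, NASH 2 or NASH 3 (edgeR adjusted p = 0.127, 0.0633, 0.0797, 0.0619 and 0.0553), nor Acacb without steatosis 2, steatosis 3, NASH 1 or NASH 2 (edgeR adjusted p = 0.109, 0.0759, 0.103 and 0.0694). Pnpla3 rested on 5 counts summed over steatosis and 50 over NASH, a ratio of 14.8 once scaled to library size (95% counting interval 5.95 to 47.7), and its call was lost without steatosis 1, steatosis 2 or NASH 1. For Srebf1, the transcription factor over this list, the log2 fold change was 0.83 (SE 0.42, edgeR adjusted p = 0.269).

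**Figure D2:**
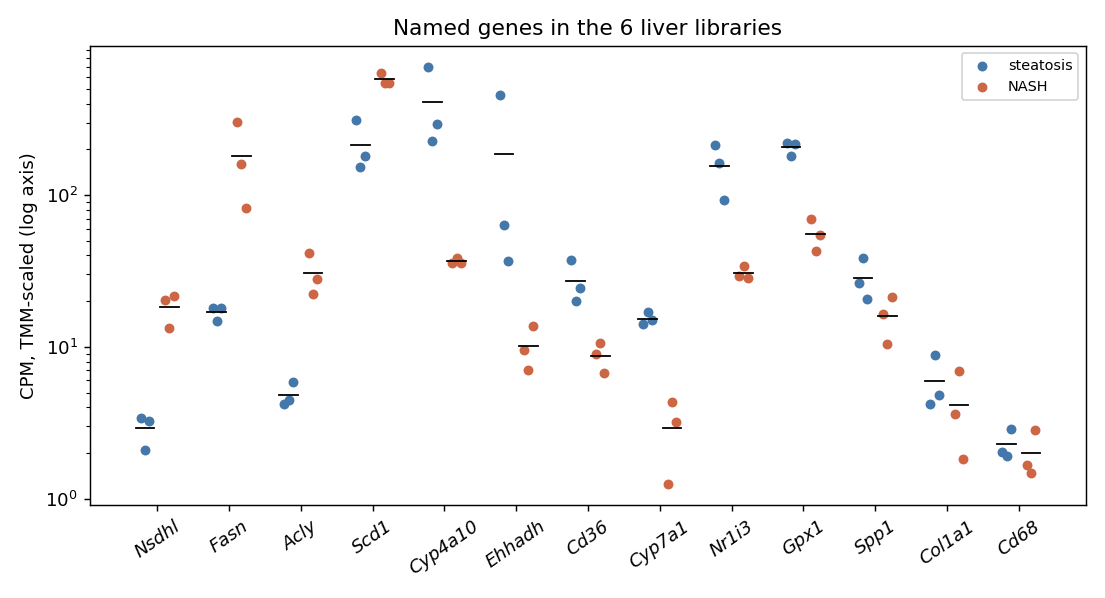
Each point is the TMM-scaled CPM of 1 liver library on a log axis for 13 named genes, steatosis in blue and NASH in red, with black bars at the group means of 3 libraries. Nsdhl to Scd1 lie higher in NASH and Cyp4a10 to Gpx1 lower, without overlap between groups, and the points of Spp1, Col1a1 and Cd68 overlap.

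The list of fatty acid oxidation genes, targets of the nuclear receptor PPARalpha, was called lower in NASH. Of 34 genes 15 fell, 0 rose and 19 did not pass (28 and 0 adjusted over the list alone), with a median log2 fold change of -1.19 (camera adjusted p = 4.73e-15; adjusted p = 0.39 with an estimated correlation). Cyp4a10, a microsomal fatty acid hydroxylase, went from 407 ± 255 to 36.5 ± 1.76 CPM (SD, n = 3 each, log2 fold change -3.48, SE 0.42, edgeR adjusted p = 0.00374). Its relative Cyp4a14 had a log2 fold change of -4.27 (SE 0.75, edgeR adjusted p = 0.015) and the peroxisomal enzyme Ehhadh one of -4.20 (SE 0.85, edgeR adjusted p = 0.0247). Steatosis 1 held 885 CPM of Cyp4a14 and 455 CPM of Ehhadh, well above the next steatosis values of 201 and 63.8 CPM, and the Ehhadh call was lost without NASH 1 (edgeR adjusted p = 0.0837), NASH 2 (0.0865) or NASH 3 (0.0588). The Cyp4a14 call was lost without NASH 1 (0.0584) or NASH 3 (0.0523). Acot1, a cytosolic acyl-CoA thioesterase with close copies beside it, had a log2 fold change of -3.43 (SE 0.47, edgeR adjusted p = 0.00642). Ech1 and Eci1, auxiliary enzymes of beta-oxidation, had log2 fold changes of -1.49 (edgeR adjusted p = 0.00966) and -1.42 (edgeR adjusted p = 0.0104). Cpt1a, of mitochondrial fatty acid entry, stood at -0.77 (edgeR adjusted p = 0.161) and did not pass.

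The list of lipid uptake and droplet genes was called lower as well. Of 27 genes 6 fell and 0 rose (14 and 1 adjusted over the list alone), with a median log2 fold change of -0.79 (camera adjusted p = 5.58e-05; adjusted p = 0.39 with an estimated correlation). The fatty acid transporter Cd36 went from 27.3 ± 9.08 to 8.75 ± 1.94 CPM (SD, n = 3 each, log2 fold change -1.63, SE 0.27, edgeR adjusted p = 0.0128). Plin4, a droplet coat protein, had a log2 fold change of -2.20 (SE 0.38, edgeR adjusted p = 0.0147), and the droplet genes Fitm1 and Fitm2 ones of -1.01 and -1.19. Of these calls that of Plin4 was lost without steatosis 1, NASH 1 or NASH 3, that of Fitm1 without any 1 of the libraries other than steatosis 3, and that of Fitm2 without steatosis 1 or any 1 NASH library. For Cidec, which promotes droplet fusion, it was -1.68 (SE 0.49, edgeR adjusted p = 0.0758), which did not pass. Without NASH 2 it was -2.35 and passed (edgeR adjusted p = 0.04).

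Drug metabolism genes gave the smallest camera p. Of 35 tested 17 fell and 0 rose (27 and 0 adjusted over the list alone), with a median log2 fold change of -1.16 (camera adjusted p = 1.82e-15; adjusted p = 0.19 with an estimated correlation). Nr1i3, the xenobiotic receptor CAR, went from 155 ± 60.2 to 30.4 ± 3.03 CPM (SD, n = 3 each, log2 fold change -2.35, SE 0.31, edgeR adjusted p = 0.00554). Its exons overlap Tomm40l on the opposite strand, which had a log2 fold change of -2.82, so the pair cannot be separated in these counts. Aldh1a1, Fmo2 and Ephx1 had log2 fold changes of -1.92, -1.69 and -1.55 (edgeR adjusted p = 0.00494, 0.00374 and 0.0058), and Ces1d one of -2.81 (edgeR adjusted p = 0.0132), a call lost without steatosis 1. Of 30 oxidative stress and glutathione genes 8 fell and 1 rose (12 and 2 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 2.07e-05; adjusted p = 0.32 with an estimated correlation). The peroxidase Gpx1 went from 206 ± 22.7 to 55.6 ± 13.3 CPM (SD, n = 3 each, log2 fold change -1.89, SE 0.25, edgeR adjusted p = 0.00554), and Prdx1 and Gpx4 had log2 fold changes of -1.40 and -1.19, the Gpx4 call being lost without steatosis 2.

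For bile acid synthesis and transport, 2 genes rose and 2 fell among 29 tested (4 and 7 adjusted over the list alone, camera adjusted p = 0.0529), and the list was called lower without steatosis 3 or NASH 2 (camera adjusted p = 0.0284 and 0.0428). Cyp7a1, the rate-limiting enzyme of the classical pathway, fell from 15.3 ± 1.47 to 2.93 ± 1.57 CPM (SD, n = 3 each, log2 fold change -2.39, SE 0.35, edgeR adjusted p = 0.00809). Cyp2c70, which makes muricholic acids in mice, rose by 1.95 (SE 0.33, edgeR adjusted p = 0.0133), a call lost without steatosis 1 or 2. The other 2, chosen after their values were seen, were Abcb11, the bile salt export pump (log2 fold change 1.20), and Hsd17b4 (-0.96). Cyp8b1, which sets the share of cholic acid, had a log2 fold change of -1.07 with an SE of 0.60 (edgeR adjusted p = 0.314). Without NASH 2 it was -2.21 and passed (edgeR adjusted p = 0.0487).

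Unfolded protein response genes were shifted up as a list (median log2 fold change 0.71, camera adjusted p = 5.58e-05; adjusted p = 0.39 with an estimated correlation), with 2 of 28 higher and 0 lower (11 and 0 adjusted over the list alone). These were Sdf2l1, an endoplasmic reticulum chaperone component, with a log2 fold change of 1.89 (edgeR adjusted p = 0.0362), and Asns, asparagine synthetase. Asns rested on 3 counts summed over steatosis and 63 over NASH, a ratio of 31.2 once scaled to library size (95% counting interval 10.2 to 155). The Sdf2l1 call was lost without any 1 of the libraries other than steatosis 3, and the Asns call without steatosis 1. Female-biased liver genes were shifted down (median -1.61, camera adjusted p = 5.69e-05; adjusted p = 0.39 with an estimated correlation), with 4 of 14 lower and 0 higher (9 and 1 adjusted over the list alone). The 4 were Cyp4a10, Acot3, Fmo2 and Cyp2b13, of which Cyp4a10 is also in the fatty acid oxidation list and Fmo2 and Cyp2b13 in the drug metabolism list. The calls of Acot3 and Cyp2b13 were lost without steatosis 1, steatosis 2, NASH 1 or NASH 3. None of the 13 mitochondrially encoded genes passed the test by itself (median 0.49, camera adjusted p = 0.000363; adjusted p = 0.71 with an estimated correlation), nor did any of 19 sinusoidal endothelial markers (median 0.32, camera adjusted p = 0.0205; adjusted p = 0.71 with an estimated correlation). By edgeR 2 of these mitochondrial and 5 of these endothelial genes had an unadjusted p under 0.05, all higher, DESeq2 called 1 in each list and limma-voom 0, and adjusted over the list alone 1 mitochondrial and 0 endothelial genes passed. The endothelial list call was lost without steatosis 2, NASH 1 or NASH 3 and in the 4 libraries with few rRNA reads. Interferon response genes had a median of -0.29 (camera adjusted p = 0.0132; adjusted p = 0.69 with an estimated correlation), with 2 of 37 lower, Igtp and Usp18, and 0 higher (7 and 1 adjusted over the list alone), and this call was lost without steatosis 3 and with the stricter filter of CPM of at least 1 in 3 libraries. The Igtp call was lost without any 1 of the libraries other than steatosis 1, and the Usp18 call without any 1 of the 6.

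**Figure D3:**
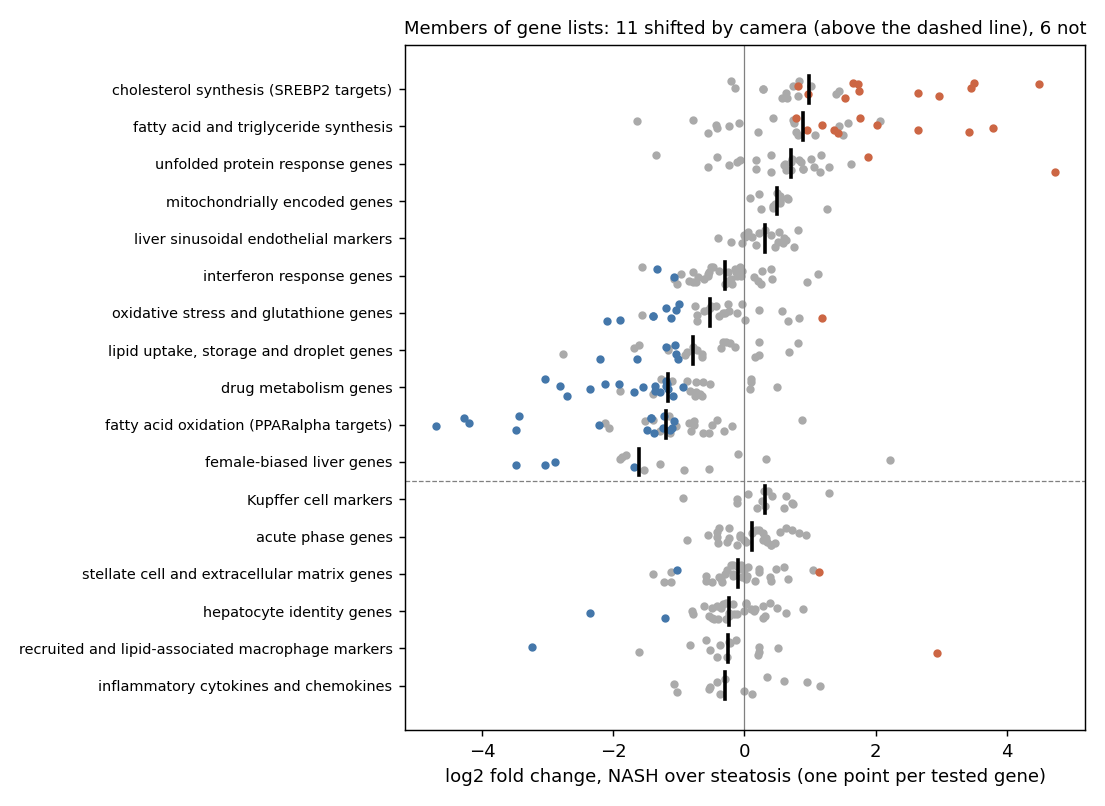
Each point is the log2 fold change (NASH over steatosis, horizontal axis) of 1 tested gene in a list, red or blue where it rose or fell by edgeR's test and grey where it did not pass, and black bars are list medians. The 11 lists called by camera stand above the dashed line, from cholesterol synthesis at a median of 0.99 to female-biased genes at -1.61, and 6 lists that were not called stand under it.

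Markers of inflammation and macrophages, which accompany NASH in histology, and of fibrosis were not called as lists by camera in the comparison of all 6 libraries. Fry, when members could move either way, called the cytokine (adjusted p = 0.00496), recruited macrophage (0.000203) and matrix lists (0.00496) but not the Kupffer list (0.397), and in 1 direction it called none of these 4. Among 13 tested cytokine and chemokine genes 0 passed edgeR's test, also adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.931). At an unadjusted p under 0.05 there were 2, both higher (Il1b at 1.16 and Ccl6 at 0.96, chosen after their values were seen), and DESeq2 and limma-voom called 0. Recruited macrophage markers had 1 higher and 1 lower gene of 16 (1 and 2 adjusted over the list alone, camera adjusted p = 0.328), Fabp5 (log2 fold change 2.94) and Atp6v0d2 (-3.24), the latter chosen after its value was seen. The Fabp5 call was lost without steatosis 1, 2 or 3, NASH 1 or NASH 3 (edgeR adjusted p = 0.129, 0.107, 0.0556, 0.104 and 0.0695), with a log2 fold change of 2.19 without NASH 1, and NASH 2 held only 1.14 CPM. Without steatosis 1 the recruited macrophage list was called lower (mean log2 fold change -0.38 against -0.27, camera adjusted p = 0.028). Of its members Plin2 and Lpl are also in the droplet list and Spp1 in the cholangiocyte list, so its values need not come from macrophages. Stellate cell and matrix genes had 1 higher and 1 lower of 35 (1 and 1 adjusted over the list alone, camera adjusted p = 0.506), Col4a2 (1.14) and Dcn (-1.03), both chosen after their values were seen. Log2 fold changes with SE were -0.83 ± 0.30 for Spp1 (edgeR adjusted p = 0.128), -0.24 ± 0.32 for Cd68 (0.702), -0.50 ± 0.43 for Col1a1 (0.527), -0.27 ± 0.27 for Col1a2 (0.59), -0.05 ± 0.24 for Tgfb1 (0.932) and 1.05 ± 0.35 for Acta2 (0.107). Kupffer cell markers (median 0.31, camera adjusted p = 0.103) included Clec4f at 0.61 ± 0.33 and Adgre1 at 0.27 ± 0.55. Without NASH 2 the Kupffer list was called higher (mean 0.54 against 0.31, camera adjusted p = 0.000983). Trem2, Gpnmb, Ccl2, Tnf, Timp1 and Tlr4 had between 0 and 34 counts per library and were too low to test. For these 6 genes, depth limits what can be said.

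Acute phase genes were not called (camera adjusted p = 0.931) and Saa1 varied widely, from 2.61 CPM in NASH 2 to 121 CPM in NASH 3. Without NASH 3 the mean log2 fold change of the list turned from 0.09 to -0.61 and passed (camera adjusted p = 0.00609). Fgf21, a hormone of the fasting and stress response, had a log2 fold change of 0.88 (SE 0.45, edgeR adjusted p = 0.266).

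Among the genes selected by fold change alone, Chrna4, a nicotinic acetylcholine receptor subunit, stood apart. It had 4 counts summed over the 3 steatosis libraries and 1187 over NASH, a ratio of 440 once scaled to library size (95% counting interval 172 to 1620). The NASH libraries held 43.4, 14.8 and 31.0 CPM (edgeR adjusted p = 0.00012). Gnat1, a transducin subunit, rose by 2.60 (SE 0.29, edgeR adjusted p = 0.00293). Selenbp2 rose by 2.43 (SE 0.51, edgeR adjusted p = 0.0275), a call lost without steatosis 1, steatosis 2, NASH 1 or NASH 3 (0.0764, 0.0676, 0.074 and 0.0643). The retinol saturase Retsat and the lipid transfer protein Osbpl5 had log2 fold changes of -2.82 (SE 0.30) and -3.44 (SE 0.38), both with an edgeR adjusted p of 0.00293. The rule also took Fam198a (log2 fold change 2.44), Eps8l1 (2.34), Cyp2a22 (-3.83), Rab30 (-3.62), Acot4 (-3.07), Pcp4l1 (-2.99), the histidine decarboxylase Hdc (-2.87) and the laminin chain Lamb3 (-2.79), with edgeR adjusted p from 0.00374 to 0.0425. The calls of Hdc, Lamb3 and Eps8l1 were lost without any 1 of the libraries other than steatosis 3, and without steatosis 1 Hdc stood at -1.86 (edgeR adjusted p = 0.0737) and Lamb3 at -2.10 (0.137). The call of Fam198a was lost without steatosis 2, NASH 2 or NASH 3, that of Rab30 without any 1 NASH library and that of Cyp2a22 without NASH 1. In GRCm38, Chrna4 lies on chromosome 2 from 181018380 to 181043546, Fasn on chromosome 11 from 120805846 to 120824547, Cyp4a10 on chromosome 4 from 115518264 to 115533649 and Cyp7a1 on chromosome 4 from 6265612 to 6275633. The identifiers of these genes in the count files are ENSMUSG00000027577, ENSMUSG00000025153, ENSMUSG00000066072 and ENSMUSG00000028240.

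The other lists were not called by camera, though fry with members moving either way also called the hepatocyte identity, adipocyte, dendritic cell, phospholipid and sphingolipid lists, and that of bile acids. In 1 direction fry called the sphingolipid list too (fry adjusted p = 0.0468). Camera adjusted p was 0.0529 for male-biased genes, 0.133 for hepatocyte identity, 0.196 for adipocyte transcripts, 0.211 for dendritic cell and MHC class II genes, 0.397 for phospholipid synthesis, 0.506 for cell cycle, 0.607 for sphingolipid metabolism and for B and plasma cells, 0.708 for the circadian clock, 0.771 for gut-derived ligand sensing and for immediate early and heat shock genes, 0.833 for glucose metabolism and for blood cells, 0.882 for cholangiocytes and 0.915 for apoptosis and p53 genes. Male-biased genes were called higher without steatosis 1 or 2 or NASH 1 or 2 (camera adjusted p = 0.00742, 0.033, 0.0198 and 0.000427), and hepatocyte identity genes lower without NASH 3 (0.0393). Median, mean and direction of the test differed in sign for cytokines (median -0.29, mean -0.08, test upward), glucose metabolism (-0.08, -0.09, upward), gut-derived ligand sensing (-0.06, 0.04, upward), acute phase genes (0.11, 0.09, downward) and blood cells (0.02, -0.05, downward). For the clock the mean, and for cholangiocytes the median, rounded to 0.00, with the test downward in both. T and NK cell, neutrophil, pancreatic acinar and muscle or mesothelial lists had too few tested members. Their summed CPM in NASH over that in steatosis was 1.08, 1.34, 1.54 and 0.532 (exact permutation p = 0.6, 0.7, 0.3 and 0.2, n = 3 each). The summed CPM of the 11 listed adipocyte transcripts went from 1130 ± 232 to 376 ± 37.9, a ratio of 0.331 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Such a sum follows its most abundant members and does not measure adipocyte content. Of the 5 tested, 2 had a positive and 3 a negative log2 fold change. Car3 alone fell by edgeR's test (log2 fold change -1.70, edgeR adjusted p = 0.00876, chosen after its value was seen), and Cidea and Fabp4 are also in the droplet list.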

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

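Of the alternatives in this part, those on mitochondrial and rRNA-like loci, on scaling without TMM, on the 4 libraries with few rRNA reads and on the rRNA share were chosen after seeing the data. The cause was not tested except where fewer libraries or more genes enter by construction. No called gene changed direction under any alternative it was tested in. Of the 54 named genes that were called, 26 were called in each fit with 1 library left out, as were 22 of the 169 higher and 60 of the 379 lower genes. Against 169 higher and 379 lower genes, DESeq2 called 310 and 569, the fit with no filter 535 and 912, and an adjusted p under 0.1 gave 445 and 784. Lower genes numbered 222 without TMM and 244 with the rRNA share as a covariate. In the 4 libraries with few rRNA reads 17 were higher and 19 lower, with 2 libraries per group. In a simulation at the measured depth, with 3 libraries per group and 200 changed genes, 23.2% of 2-fold changes were recovered. The cause of the low share was not tested, and recovery may differ where more genes change. Leaving out 1 library gave 29 to 170 higher and 77 to 298 lower genes. Of the lists, 10 to 15 were called under the other fits in which they were tested, against 11, but 0 with an estimated correlation, 6 by fry in 1 direction and 18 by fry in either.

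The replicate number as a block gave 153 higher and 313 lower genes and 15 lists. With the block, 4 lists and 3 named genes that were not called without it passed, and 1 named gene lost its call. The numbers were not treated as pairs, because the labels state no litter, cage, batch or day behind them. Residuals of libraries with the same number correlated at 0.035, -0.012 and 0.071. Not every library correlated best with its own number.

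Sign changes were seen for genes and lists that were not called, most with values near 0. Without TMM, Tgfb1 stood at 0.07, and list means at 0.01 for inflammatory cytokines, 0.05 for apoptosis and p53, 0.10 for the circadian clock, 0.03 for glucose metabolism and 0.07 for blood cells. In the 4 libraries Col1a1 stood at 0.23, Col1a2 at 0.10, gut-derived ligand sensing at -0.06, blood cells at 0.11 and acute phase genes at -0.57 (camera adjusted p = 0.00703). The acute phase mean was -0.06 with the block and -0.27 with the rRNA covariate, against 0.09. Circadian genes moved from 0.00 to 0.01 with DESeq2's size factors and with the loci left out, and stood at 0.00 with the stricter filter, where blood cells were at 0.00 and cell cycle genes at -0.13. With 1 library left out, ranges were -0.12 to 0.09 for Tgfb1, -2.33 to 0.47 for Saa1, -0.55 to 0.00 for Cd68, -0.61 to 0.37 for acute phase, -0.10 to 0.01 for apoptosis and p53, -0.23 to 0.16 for glucose metabolism, -0.36 to 0.03 for immediate early genes, -0.21 to 0.08 for blood cells, -0.21 to 0.25 for circadian genes, -0.37 to 0.06 for inflammatory cytokines, -0.29 to 0.99 for B and plasma cells, -0.39 to 0.64 for cell cycle and -0.02 to 0.14 for gut-derived ligand sensing.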

Other observations

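The tests in this part on feeding state, liver zone, hepatocyte share, marker depth, sex and gene families were chosen only after the values they bear on had been seen, in full or in part. Nuclear-encoded subunits of the respiratory chain were shifted down as a family in NASH: of 77 tested 21 fell and 0 rose, with a median log2 fold change of -0.70 (camera adjusted p = 1.67e-15 over 15 families and lists; adjusted p = 0.23 with an estimated correlation). The largest falls by edgeR's test were Atp5g3 (-1.77), Ndufa4 (-1.60), Uqcrh (-1.43) and Cox8a (-1.39). The 13 mitochondrially encoded subunits of the same chain had a median of 0.49, in the other direction, but 0 of them passed edgeR's test. Their list means overlapped between the groups (exact permutation p = 0.2), and camera with an estimated correlation gave an adjusted p of 0.71. Their share of all counts was 72.3% ± 5.01 in steatosis and 75.9% ± 12.1 in NASH (SD, n = 3 each, exact permutation p = 0.8). Called lower genes had a median transcript length of 2143 bases against 3255 for all tested genes and 3405 for called higher genes. After a trend on length and GC content was removed the respiratory chain median was -0.56, and that of 60 cytosolic ribosomal protein genes, 4 of which fell and 0 rose, moved from -0.35 to -0.14. Under the other scalings the respiratory chain median lay between -0.71 and -0.58.

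Among 46 cytochrome P450 genes 13 fell and 1 rose, Cyp2c70. Carboxylesterases had 4 of 13 lower and acyl-CoA thioesterases 4 of 9, with 0 higher in each, and the medians of these 3 families stayed below 0 under each scaling. Camera adjusted p was 1.42e-06, 0.00042 and 2.28e-05 for the 3, and 0.082, 0.082 and 0.23 with an estimated correlation. Members that fell, such as Cyp4a10, Ces1d and Acot1, are also in the PPARalpha or drug metabolism lists, so the families are not separate findings. Of the complement genes 2 of 19 rose, C6 (log2 fold change 1.17) and C9 (1.26), and the family was not called (camera adjusted p = 0.114). Calls among the 18 clock genes included Nr1d1, which rose (1.76), and Hlf, which fell (-1.07).

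Synthesis genes higher and PPARalpha target genes lower made a gap of 2.65 on the log2 scale between the means of these lists. Carry-over of rRNA as the whole cause is argued against, since the 4 libraries with few rRNA reads held 104.6% of the gap, and so is a trend on transcript length and GC content, since 97.9% was left once it was removed. A lower share of hepatocytes would need their identity genes to fall as far as the PPARalpha targets, at a median of -1.19. The identity genes had a median of -0.23 (95% bootstrap interval over genes -0.36 to 0.03). The intervals in this paragraph resample the genes of a list and hold no variation between libraries. A different feeding state at collection may contribute and cannot be told apart from disease, as 18 fasting-induced genes had a median of -0.37 with an interval of -0.58 to 0.10. By edgeR's test 1 of the 18 rose, Sds (log2 fold change 1.62, edgeR adjusted p = 0.0457), which is also among the periportal genes, and 0 fell (camera adjusted p = 0.497). Of the 18, 9 are in other fixed lists, among them Ppargc1a in the PPARalpha list itself, and the 9 in no fixed list had a median of -0.21. Sampling of another liver zone also stays open. The 19 pericentral genes (4 of them in other lists) lay below 20 periportal ones (6 in other lists) by a median difference of -1.07 (interval -1.35 to -0.44). By edgeR's test 7 pericentral genes fell and 0 rose (camera adjusted p = 1.42e-06, or 0.082 with an estimated correlation). The 7 included Cyp1a2 and Cyp2e1, which are also in the drug metabolism list. Of the periportal genes 2 rose and 0 fell (camera adjusted p = 0.135). The test of the median difference accepted either sign, so it does not show whether this direction would give the gap or oppose it. The progression to NASH by which the mice were sorted remains an untested explanation.

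Camera called none of the cytokine, recruited macrophage, Kupffer and matrix lists in all 6 libraries, and this was set against the low depth over nuclear genes. Over the 63 tested cytokine, recruited macrophage and matrix markers the mean log2 CPM was lower by 0.15 in NASH (difference -0.15), with an exact one-sided 95% upper bound of 0.02. With the 15 Kupffer cell markers added the difference was -0.07 and the bound 0.16. The bounds speak against a doubling of the mean only. Markers moved both ways, so the bounds do not show whether a doubling of a single marker could be seen, and depth stays a possible explanation there. Il1b (1.16), Acta2 (1.05) and the Kupffer marker Cd163 (1.29) were more than 2-fold higher without passing. More than 2-fold lower without passing were Plin2 (-1.61), which is also in the droplet list, Loxl1 (-1.40), Lum (-1.22), Timp2 (-1.12), Lgals1 (-1.12), Cxcl9 (-1.07) and Il1rn (-1.03). Trem2, Ccl2, Tnf and others fell under the filter. A histological class assigned to the wrong libraries could not be tested, since no gene was targeted in this design.

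Lower expression of female-biased genes in NASH could come from mice of both sexes. This is argued against by the Y-linked gene Eif2s3y, at 17.3 CPM or more in each of the 6 libraries, and by Xist, with at most 1 count. Overlap with the PPARalpha and drug metabolism lists, through Cyp4a10, Fmo2, Cyp2b13 and Cyp2b9, may contribute. Of 10 tested members in neither list 8 had a negative log2 fold change (median -1.10), but only Acot3 passed, a call lost in 4 of 6 fits with 1 library left out, and the 10 were not tested as a list. Acot3 lies on chromosome 12 close to Acot4 (-3.07) and to Acot1 (-3.43), which is in the PPARalpha list. Reads may have been split between these copies, so the Acot3 call does not show a shift separate from that list. The source stays open.

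The number of splits of the 6 libraries into 3 and 3 is 10, too few for a share under 0.05. The real split, which was 1 of the 10, gave 169 higher and 379 lower genes, and the highest of the others gave 3.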
